A study of Vitis vinifera with 16 samples.

How the data were processed

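Total RNA from ovules of 2 grape varieties, Muscat Hamburg (MH) and Zhongpu No. 18 (ZP), was sequenced on an Illumina NovaSeq X Plus, per the labels. Variety and day were taken from the labels, which give 4 days and 2 libraries per group. The labels do not say that the 2 libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

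The authors deposited FPKM values per gene and library, per the file headers, with gene positions and descriptions. The aligner, the counting tool and the genome build were not given in the sources used here, nor was it stated whether counting used strand. Of 13411 genes, 12540 (93.5%) were named in the RefSeq annotation of assembly ASM3070453v1, all with the same start and end, and 825 were gene models of the authors' own. The genes held 47.7% of the 25109 protein-coding RefSeq genes. No gene had a range over the group means under 0.15 (log2), and the median range was 1.85, so the deposited genes look selected for variation by a rule not given in the sources used here. Shares and counts of called genes apply to this selection, which is also the background of the list tests. All per-sample columns were used.

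The design written before the data were examined assumed read counts first. Its fallback for normalized values (FPKM) was used. Genes with at least 1 FPKM in at least 2 libraries were kept (12637), and limma with a mean-dependent prior variance was fitted to log2(FPKM + 1), with 1 mean for each of the 8 groups over all 16 libraries and 8 residual degrees of freedom. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Contrasts were ZP minus MH on each day and averaged over the 4 days, and day 61 minus day 35 in each variety. The interaction was an F-test of 3 terms. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05 with no limit on the fold.

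The 28 gene lists were written as patterns on gene descriptions before the data were examined. One pattern was corrected after the descriptions, but no test, had been seen, because it matched parts of other words. The lists cover monolignol biosynthesis, laccases, class III peroxidases, dirigent proteins, secondary wall polysaccharides and regulators, vascular markers, ovule and seed coat regulators, endosperm and embryo markers, and seed storage and desiccation. They also cover flavonoids and proanthocyanidins, anthocyanin (skin) markers, stilbene synthases, pericarp ripening, photosynthesis, sugar, lipid and wax, and the hormones auxin, cytokinin, gibberellin, ethylene and abscisic acid. The last are cell cycle and histones, cell death and senescence, heat shock, pathogenesis-related, ribosomal proteins and organelle RNA. A list is only as good as its descriptions. Lists were tested with camera (preset correlation 0.01) over the tested genes, adjusted over lists within a comparison, and again with an estimated correlation.

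Genes were named by a rule fixed before the data were examined. It took the member with the highest mean of each of the 11 monolignol steps, called or not; 1 of these genes is not reported here. From other lists that passed camera or had 3 or more called members it took up to 4 called members with the largest change and a mean of at least 10 FPKM in a compared group, and some of these were left out for length. Over all genes it took the 5 largest rises and 5 largest falls with a description, a mean of at least 10 FPKM and no overlap between the libraries compared. Genes described as AGL11 were also to be named; there were 0. Members of families with near-identical copies (storage proteins, heat shock proteins, laccases, stilbene synthases, chlorophyll a-b binding proteins) and genes that overlap another gene are uncertain, since the way shared reads were assigned was not given.

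Depth was recovered from the values. In 3493 genes (26.0%) the values of all libraries were whole multiples of a step, within 0.06 of a step and up to 400 steps, and the steps gave the relative depth of the libraries. The scale came from transcript spans, with 641 of 2995 genes at the most common product of step and span, so the depths in fragments are estimates. On simulated values the recovered depths were off by at most 1e-06%. The variance between the 2 libraries of a group was 1.46 to 3.48 times the sampling noise in the median gene, so no library was counted as a copy of another.

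The tests were tried on simulated data. At day 35, known sets of the 12637 genes were changed by 0.5, 1 and 2 (log2). They were picked among genes with a mean log2(FPKM + 1) of at least 3. Of these sets, 31.8%, 80.6% and 97% were called. So were 12 unchanged genes, 7.89% of all calls. For the interaction the shares were 3%, 34.3% and 95.5%, with 4 unchanged genes called (4.3%). With none moved 0 of 28 lists were called, and a moved list of 24 genes had an adjusted p of 2.63e-60. This says little on real lists, few of whose calls held with an estimated correlation.

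Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, quantile normalization, an added limit of 1 on the absolute log2 change (for the interaction an adjusted p under 0.01) and fits of only the 2 groups compared. So were the replicate number as a block, each library left out in turn, and for lists an estimated correlation, fry and the block. Median-ratio scaling of the FPKM, rescaling without the seed storage and desiccation list, an exchanged block, a block within each variety and camera after quantile normalization were chosen after seeing the data. The block within each variety was added because libraries of the same number deviated together within MH (correlations of 0.408 to 0.728 between groups). Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.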

Results

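RNA from grape ovules was sequenced in 2 varieties, Muscat Hamburg (MH) and Zhongpu No. 18 (ZP), at day 35, 45, 55 or 61 counted from flowering. Each of the 8 groups held 2 libraries, 16 in all. The study is about lignin biosynthesis in ovules of seeded grapes and of stenospermocarpic grapes, in which seeds are fertilised but stop growing early. The labels do not state which of the varieties is seedless; Muscat Hamburg is known as a table grape with seeds. The ovules were frozen with the skin kept on. The deposited table gave an FPKM value (fragments mapped to a gene, scaled by transcript length and by library size) for 13411 genes, of which 12637 reached 1 FPKM in at least 2 libraries and were tested. Below, a level is the mean FPKM ± SD of a group (n = 2 libraries), and a change is a difference of log2(FPKM + 1) ± standard error, given as ZP minus MH or as day 61 minus day 35. Adjusted p-values come from limma with Benjamini-Hochberg adjustment over the 12637 genes.

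The steps between low FPKM values placed the depth of the libraries between 1.99e+07 and 2.99e+07 fragments, so that 1 fragment in a transcript of 1 kb was worth between 0.033 and 0.05 FPKM. The median SD between the 2 libraries of a group was between 0.049 on the log2 scale (ZP at day 35) and 0.156 (MH at day 55). In a principal component analysis of the 16 libraries, PC1 held 64.1% of the variance and parted the 8 MH libraries from the 8 ZP libraries. PC2 held 17.4% and ordered the days within each variety.

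**Figure D1:**
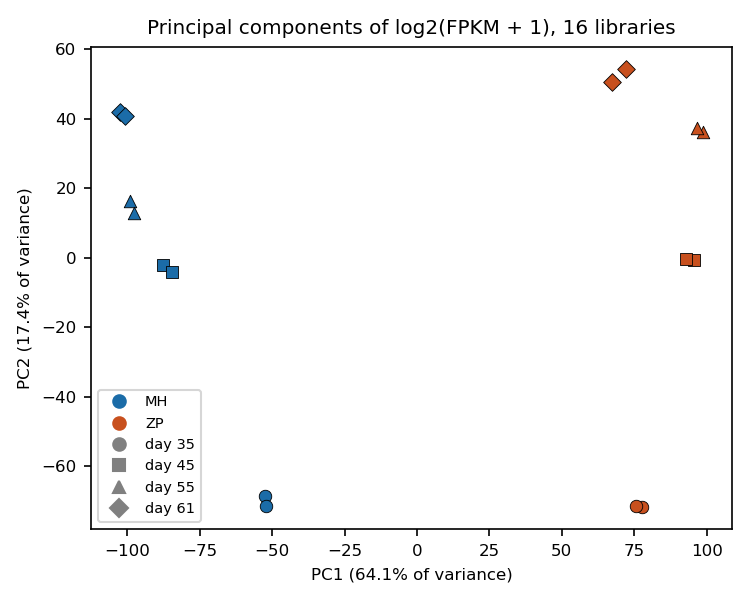
Scores of the 16 libraries on the first 2 principal components of log2(FPKM + 1), with PC1 (64.1% of the variance) on the x axis and PC2 (17.4%) on the y axis. Each point is 1 library, coloured by variety and marked by day after flowering; the MH libraries lie at -102.4 to -52.1 on PC1 and the ZP libraries at 67.4 to 98.7.

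Genes of seed storage took very different shares of the libraries. The 78 tested genes of the seed storage and desiccation list held 21.3% and 17.6% of the summed FPKM in the MH libraries of day 35, and 46.8% and 41.8% at day 45. At days 55 and 61 their share in MH lay between 37.9% and 43.2%. In ZP it was 0.2% in both libraries of day 35, 0.4% to 0.5% at days 45 and 55, and 1% and 1.7% at day 61. The 10 most abundant genes of each library held 22.6% to 58.4% of the summed FPKM in MH and 9.1% to 15.6% in ZP. Because FPKM is a share of all fragments, each variety comparison is given with the median over all tested genes. Where it matters, it is also given after median-ratio scaling, chosen after seeing the data. The scaling assumes most genes unchanged, yet 74.6% to 88.7% were called between the varieties. Near-even splits after it or quantile normalization are built in.

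**Figure D2:**
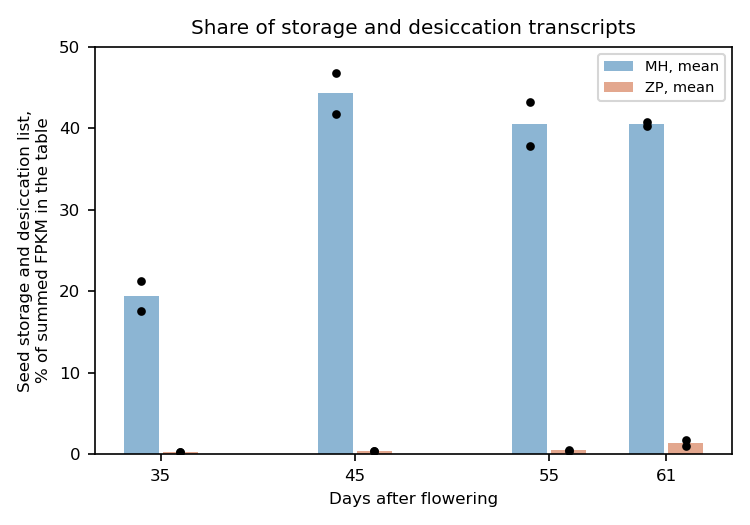
Share of the summed FPKM (y axis, percent) taken by the seed storage and desiccation list against days after flowering (x axis). Bars are means of 2 libraries, blue for MH and orange for ZP, and points are single libraries, which lie between 17.6% and 46.8% in MH and between 0.2% and 1.7% in ZP.

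Averaged over the 4 days, transcripts of seed storage proteins were lower in ZP. Cruciferin CRU1 (LOC100246409), an 11S seed storage globulin, differed by -11.74 ± 0.96 and stood at 61791 ± 401 FPKM in MH at day 45 and at 0.173 and 44.4 FPKM in the 2 ZP libraries. The 2S albumin gene (LOC100252101) differed by -10.37 ± 0.65, the basic 7S globulin gene (LOC100240860) by -9.83 ± 0.68, the non-specific lipid-transfer protein A-like gene (LOC100266074) by -10.23 ± 0.75 and an endochitinase gene (LOC100255900), of a family that cleaves chitin, by -9.28 ± 0.68. Higher on average in ZP were an organ-specific protein P4-like gene (LOC100852930, 6.25 ± 0.08) and PR1, a basic form of pathogenesis-related protein 1 (6.25 ± 0.12). So were a replication protein A subunit gene that overlaps another annotated gene (LOC100852586, 6.13 ± 0.06), a lipid transfer protein precursor (LOC100232872, 6.05 ± 0.14) and MLP-like protein 28 (LOC100262819, 6.00 ± 0.09). Adjusted p-values of these 10 genes were at most 4.39e-08, and the libraries of the varieties did not overlap.

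Among the lists fixed beforehand, seed storage and desiccation was lower in ZP, with 53 of 78 genes lower and 21 higher over all genes tested and the same counts adjusted over the list alone (camera adjusted p = 3.78e-12). Photosynthesis was higher, with 38 of 39 genes higher and 1 lower, and the same counts adjusted over the list alone (camera adjusted p = 2.01e-05). Photosystem I subunit N (LOC100232935) was higher by 4.52 ± 0.07 (adjusted p = 3.25e-15). The exception was a Rubisco small chain gene (LOC100256536, -4.09 ± 0.12, adjusted p = 7.39e-13). Of the secondary wall polysaccharide genes, which make the cellulose and xylan of thick walls, 25 of 27 were higher and 1 lower (25 and 1 adjusted over the list alone, camera adjusted p = 0.026). COBRA-like protein 4 (LOC100244586) was higher by 3.11 ± 0.07 and the cellulose synthase subunits CESA7 (LOC100248512) and CESA8 (LOC100261696) by 2.45 ± 0.06 and 2.38 ± 0.07. Pericarp ripening markers, a sign of other berry tissue, were higher in 112 of 131 cases and lower in 14 (the same adjusted over the list alone, 93 and 25 after median-ratio scaling, camera adjusted p = 0.00446). With an estimated correlation none of these 4 calls held. The adjusted p was 0.271 for storage and pericarp markers and 0.474 for the others.

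Of single genes on average, a vacuolar-processing enzyme gene (LOC100251259), of the proteases that mature vacuolar proteins, was higher in ZP by 4.76 ± 0.08, while another (LOC100260773) differed by -4.68 ± 0.10. The soluble beta-fructofuranosidase gene (LOC100256970), an invertase that splits sucrose, was higher by 4.30 ± 0.05, and the sugar transporter gene SWEET14 (LOC100266643) differed by -4.81 ± 0.08. ABSCISIC ACID-INSENSITIVE 5-like protein 1 (LOC100255346), a bZIP factor of the abscisic acid response, differed by -4.79 ± 0.14. All 6 ovule and seed coat regulators tested were higher (6 and 0 adjusted over the list alone; 4 higher and 2 lower after median-ratio scaling). They included TRANSPARENT TESTA 1 (LOC100264302, 3.20 ± 0.06, listed at 0 in MH at day 55), TRANSPARENT TESTA 16 (LOC100244209, 2.78 ± 0.07) and MADS4, which overlaps another annotated gene (2.02 ± 0.07). That list was not called by camera (adjusted p = 0.189, and 0.504 with an estimated correlation). NAC domain-containing protein 37 (LOC100243701), a regulator of vessel walls, was higher by 2.47 ± 0.07 (3.79 with a pseudocount of 0.1). Laccase-17 (LOC100251378, listed at 0 in MH at day 45) and a laccase-4 gene (LOC100267265), which encode oxidases that link monolignols, were higher by 2.83 ± 0.08 and 1.97 ± 0.08. With a pseudocount of 0.1 laccase-17 was at 5.83 and TRANSPARENT TESTA 1 at 4.97. After median-ratio scaling MADS4 was at 1.28 and LOC100267265 at 1.27. The 11 genes given with a change here had adjusted p-values of at most 3.22e-11.

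Lignin is built from monolignols, and the most abundant gene of 10 steps was followed whatever its test. F5H (cytochrome P450 84A1, LOC100250277) was lower in ZP at -2.40 ± 0.11 and stood at 18 ± 1.61 FPKM in MH and 2.48 ± 0.0555 FPKM in ZP at day 35. Higher in ZP were CAD (LOC100257308, 1.63 ± 0.06) and HCT (LOC100265530, 1.20 ± 0.15), and lower were 4CL (4-coumarate-CoA ligase 2, -0.60 ± 0.09, a gene that overlaps another), CCoAOMT (LOC100243978, -0.43 ± 0.07) and PAL (LOC100241575, -0.25 ± 0.06), the entry enzyme. The 6 genes had adjusted p-values of at most 0.00132. C3H (cytochrome P450 98A2, LOC100263633) was higher by 0.45 ± 0.11 (adjusted p = 0.00142). Values without a call were -0.10 ± 0.06 for C4H (LOC100253493), 0.07 ± 0.06 for CCR (LOC100255334) and 0.38 ± 0.19 for CSE (LOC100248095, adjusted p = 0.0783). Median-ratio scaling gave -0.99 for PAL, -1.33 for 4CL, 0.50 for HCT, -1.17 for CCoAOMT and 0.89 for CAD. The call of C3H was lost under that scaling (-0.27), quantile normalization (-0.07) and rescaling without the storage list (0.19). Calls were gained for C4H (-0.84, -0.21 and -0.38) and CCR (-0.67, -0.30 and -0.20). CSE was called without MH day 35 replicate 1 (0.48), MH day 45 replicate 1 (0.47), MH day 55 replicate 1 (0.52), MH day 61 replicate 1 (0.46) or ZP day 55 replicate 1 (0.47). Of all 69 monolignol genes 34 were higher and 26 lower (the same adjusted over the list alone; 29 and 34 after median-ratio scaling); the list was not called (camera adjusted p = 0.189, 0.474 with an estimated correlation), its test pointing down while its median was 0.22, or -0.26 after that scaling.

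In the coordinates of the table, which for the named genes equal those of the RefSeq assembly ASM3070453v1, the monolignol genes lie on chromosome and positions 6, 3281243 to 3284788 (PAL), 6, 8894765 to 8898590 (C4H), 16, 2094540 to 2099713 (4CL) and 9, 19333207 to 19336512 (HCT). The next are at 8, 12894816 to 12897886 (C3H), 9, 5472963 to 5474450 (CSE), 7, 27236226 to 27238029 (CCoAOMT), and the last at 3, 464876 to 466864 (F5H), 6, 2868064 to 2874759 (CCR) and 3, 6188157 to 6189943 (CAD). Cruciferin CRU1 lies on chromosome 7, 6658898 to 6660930, and legumin A (LOC100241281) on 7, 6653634 to 6655702. The 2S albumin gene lies on 19, 5917560 to 5918293 and the basic 7S globulin gene on 14, 3309105 to 3311151. All of these are annotated as protein-coding, and each value is a total over the gene, with no split into exons.

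**Figure D3:**
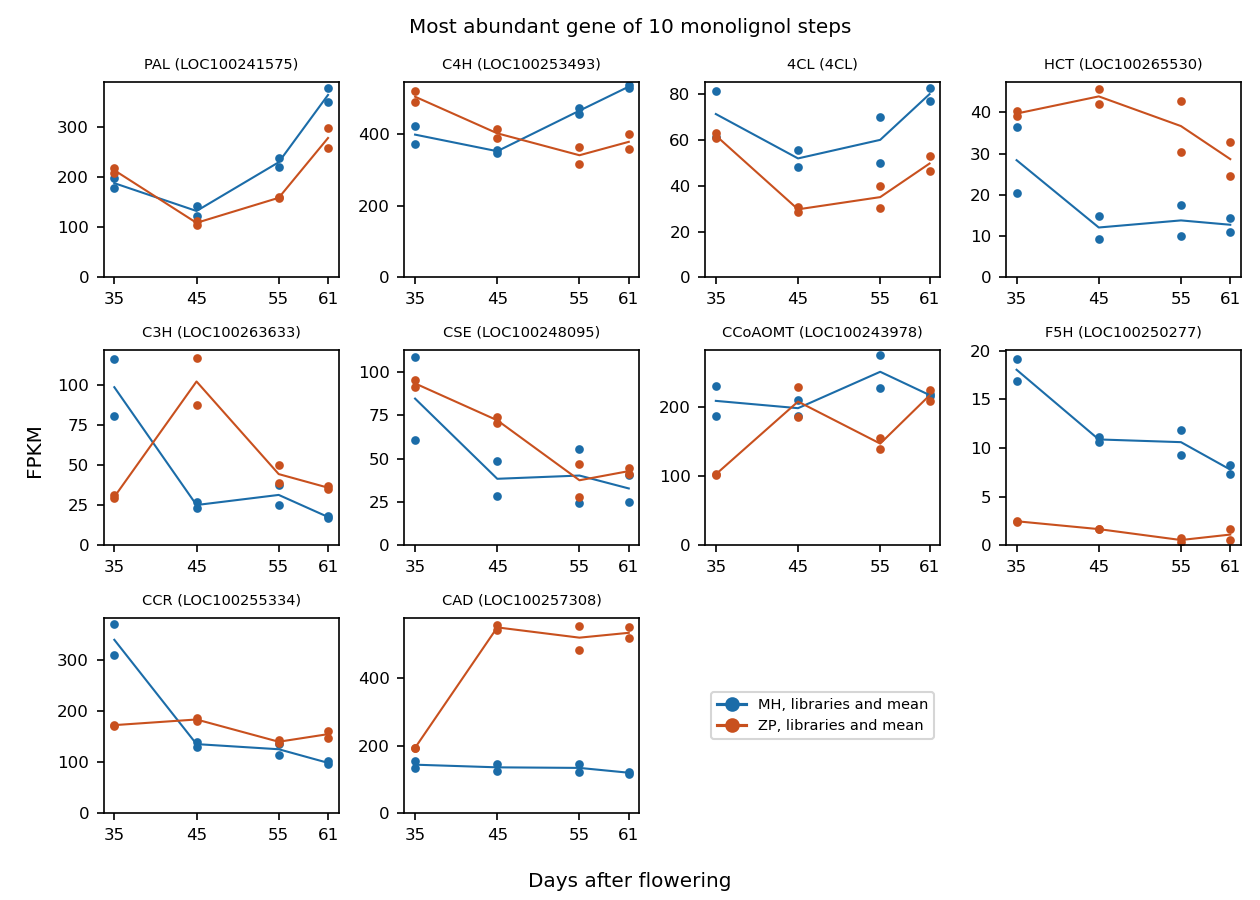
Level of the most abundant gene of 10 monolignol steps (y axis, FPKM, linear scale from 0) against days after flowering (x axis), 1 panel per step. Points are single libraries and lines join the means of 2 libraries, coloured by variety; F5H (LOC100250277) was lower in ZP on each day, with differences of -2.45, -2.15, -2.90 and -2.11 on the log2 scale.

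Averaged over the days, 11204 of 12637 genes were called, 7786 higher and 3418 lower in ZP, with a median of 0.583 over all genes. After quantile normalization the split was 5898 higher and 5490 lower, and after median-ratio scaling 5829 and 5410. Leaving the storage list out of the total gave 6997 and 4179.

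At day 35 storage transcripts were already abundant in MH and near the lower end in ZP, where the first 3 genes named lay almost wholly in replicate 2. Cruciferin CRU1 (LOC100246409) stood at 28641 ± 3613 FPKM in MH and at 0.0589 and 32 in replicates 1 and 2 of ZP, 2S albumin (LOC100252101) at 18470 ± 4728 against a listed 0 and 19, legumin A (LOC100241281) at 15757 ± 2524 against 0.0191 and 18.2 and an oleosin (LOC100249321), a coat protein of oil bodies, at 2718 ± 999.9 against 0.365 and 0.634. Their differences were -12.24 ± 1.92, -11.99 ± 1.29, -11.79 ± 0.99 and -10.78 ± 0.50. Sucrose synthase 2 (LOC100243135), which cleaves sucrose, differed by -10.51 ± 0.26. The largest rises of the fixed rule were an aspartyl protease AED3 gene (LOC100252287, 8.25 ± 0.17), ornithine decarboxylase (LOC100232922, 8.07 ± 0.18), which starts polyamine synthesis, a thaumatin-like protein (LOC100261232, 7.87 ± 0.35), the organ-specific protein P4-like gene (LOC100852930, 7.53 ± 0.16) and a proline-rich protein DC2.15 gene (LOC100267804, 7.34 ± 0.35). Adjusted p-values of these 10 genes were at most 6.04e-05, and the libraries of the varieties did not overlap.

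Of 77 heat shock genes, which encode chaperones, 51 were higher and 11 lower in ZP (the same adjusted over the list alone, camera adjusted p = 0.00625). Examples were the class IV protein (LOC104881029, 5.87 ± 0.25; 7.71 ± 1.39 FPKM in MH and 503 ± 12.8 in ZP) and a class I protein (LOC100259921, 5.66 ± 0.20). Of 84 cell cycle and histone genes 58 were lower and 13 higher (59 and 13 adjusted over the list alone, camera adjusted p = 3.27e-05), among them cyclin-D4-2 (LOC100265861, -3.32 ± 0.18) and histone H2A variant 1 (LOC100257988, -2.32 ± 0.24). Cell death and senescence genes were higher in 22 of 29 cases and lower in 2 (the same adjusted over the list alone, camera adjusted p = 0.00732). The vacuolar-processing enzyme gene LOC100251259 stood at 3531 ± 7.8 FPKM in ZP and 44.5 ± 2.48 in MH, a difference of 6.28 ± 0.17. Photosynthesis genes were higher in 38 cases and lower in 1 of 39 (the same adjusted over the list alone, camera adjusted p = 1.89e-07), with a median of 2.41, or 2.11 after median-ratio scaling. A chlorophyll a-b binding protein (LOC100250504) differed by 4.52 ± 0.20. Pericarp ripening markers moved with these lists, 89 of 131 higher and 28 lower (90 and 28 adjusted over the list alone, camera adjusted p = 0.00259), including GRIP22 (5.43 ± 0.22). The storage list had 51 genes lower and 8 higher of 78 (the same adjusted over the list alone, camera adjusted p = 1.02e-08). The adjusted p with an estimated correlation was 0.221 for heat shock, cell cycle, pericarp markers and seed storage, 0.424 for cell death and 0.514 for photosynthesis, so that no list was called.

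Among single genes at day 35, WRI1 (LOC100250488), listed under ethylene by its description but known as a regulator of seed oil synthesis, differed by -6.95 ± 0.20 (adjusted p = 8.84e-12) and the embryo gene WUSCHEL-related homeobox 2 (LOC100263784) by -5.20 ± 0.19 (adjusted p = 6.98e-11). Of the genes that act after the monolignols are made, peroxidase 51 (LOC100254910) was higher by 6.29 ± 0.14, dirigent protein 23 (LOC100264136) by 6.39 ± 0.14 and laccase-17 by 3.57 ± 0.17 (6.65 with a pseudocount of 0.1). Among wall genes, COBRA-like protein 4 (LOC100244586) was higher by 1.95 ± 0.15, the wall regulator MYB83 (LOC100243210) was higher by 1.64 ± 0.14, and fasciclin-like arabinogalactan protein 11 (LOC100250171) was lower at -2.42 ± 0.20. The 6 last genes had adjusted p-values of at most 1.83e-07.

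Along the monolignol pathway at day 35, F5H (-2.45 ± 0.22, adjusted p = 2.45e-07), C3H (-1.65 ± 0.22, adjusted p = 1.12e-05), CCoAOMT (-1.01 ± 0.15, adjusted p = 2.85e-05) and CCR (-0.97 ± 0.12, adjusted p = 7.76e-06) were lower in ZP. CAD and C4H were higher by 0.43 ± 0.13 (adjusted p = 0.00824) and 0.34 ± 0.12 (adjusted p = 0.021). PAL at 0.19, 4CL at -0.19, HCT at 0.53 and CSE at 0.20 did not pass. The CAD call was lost after median-ratio scaling (0.13), quantile normalization (0.19) and rescaling without the storage list (0.24). The C4H call was lost after the first (0.04) and last (0.15). It was also lost without MH day 35 replicate 2 (0.25), ZP day 35 replicate 1 (0.30) or ZP day 35 replicate 2 (0.38). The CAD call was lost too without MH day 35 replicate 2 (0.33), while HCT was called without MH day 35 replicate 1 (0.93). Of the 69 genes of the list 26 were higher and 29 lower (the same adjusted over the list alone; 18 and 31 after median-ratio scaling; camera adjusted p = 0.218, 0.514 with an estimated correlation).

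At day 35, 9718 genes were called, 5793 higher and 3925 lower, with a median of 0.236 over all genes. The split was 5146 and 4573 after quantile normalization, and 4865 and 4694 after median-ratio scaling.

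At day 45 the storage genes reached their highest share in MH. 2S albumin (LOC100252101) stood at 71914 ± 42132 FPKM in MH and 1.78 and 19.5 in the ZP libraries (-13.08 ± 1.29), and cruciferin CRU1 differed by -13.05 ± 1.92. The lipid-transfer protein LOC100266074 differed by -12.33 ± 1.50, the endochitinase LOC100255900 by -12.18 ± 1.36 and the basic 7S globulin LOC100240860 by -11.92 ± 1.36. These last 4 genes stood at 0.0731 to 0.226 FPKM in replicate 1 of ZP and at 11.1 to 44.4 in replicate 2. Higher in ZP were a pectinesterase inhibitor (LOC104877746, 8.79 ± 0.22; 3.07 ± 0.71 FPKM in MH and 1784 ± 126 in ZP), the copper protein basic blue (LOC100248861, 7.54 ± 0.13), the organ-specific P4 genes LOC100852930 (7.47 ± 0.16) and LOC100853060 (7.39 ± 0.15) and the DC2.15 gene LOC100267804 (7.41 ± 0.35). Adjusted p-values of these 10 genes were at most 3.01e-05, and no library of 1 variety overlapped the other.

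At day 45, 25 of 27 wall polysaccharide genes were higher in ZP and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.00169, 0.49 with an estimated correlation), with a median of 2.34, or 1.60 after median-ratio scaling. CESA7 (LOC100248512) stood at 232 ± 29 FPKM in ZP and 17.4 ± 1.13 in MH (3.66 ± 0.13), and glucuronoxylan 4-O-methyltransferase 3 (LOC100255018) and COBRA-like protein 4 (LOC100244586) were higher by 3.89 ± 0.14 and 3.89 ± 0.15. Of 15 secondary wall regulators 14 were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.028, 0.49 with an estimated correlation), with NAC domain-containing protein 37 (LOC100243701) at 3.56 ± 0.15 and MYB83 at 3.01 ± 0.14. The laccase-4 genes LOC100240808 and LOC100267265 were higher by 4.23 ± 0.19 and 3.53 ± 0.17, dirigent protein 22 (LOC100265620) by 4.38 ± 0.16 and the xylem cysteine protease XCP1 (LOC104877917) by 3.39 ± 0.11. Of 24 laccases 15 were higher and 2 lower (the same adjusted over the list alone; 12 and 8 after median-ratio scaling; camera adjusted p = 0.344, 0.696 with an estimated correlation). The adjusted p-values of the 9 genes named here were at most 4.42e-10. Markers of other tissues moved with these lists: of 14 vascular markers 11 were higher and 0 lower (12 and 0 adjusted over the list alone; 10 and 1 after median-ratio scaling; camera adjusted p = 0.235), and of 25 skin markers 20 and 3 (the same adjusted over the list alone; 19 and 3; 0.0609), both at 0.49 with an estimated correlation.

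Heat shock genes had the opposite sign from day 35. At day 45, 48 of 77 were lower in ZP and 12 higher (the same adjusted over the list alone, camera adjusted p = 6e-13, and 0.0118 with an estimated correlation), with a median of -0.82, or -1.74 after median-ratio scaling. The class I genes LOC100249533 and LOC100253085 differed by -4.85 ± 0.24 (adjusted p = 8.52e-10) and -4.53 ± 0.14 (adjusted p = 1.74e-11). Photosynthesis again had 38 higher and 1 lower of 39 (the same adjusted over the list alone, camera adjusted p = 0.00148, 0.513 with an estimated correlation), with LOC100250504 at 3.55 ± 0.20. Of the pericarp ripening markers 13 of 131 were lower, 13 were not called and the others were higher (13 lower and 13 not called adjusted over the list alone, camera adjusted p = 0.00975, 0.288 with an estimated correlation). Their members moved apart: a polygalacturonase gene (LOC100263206), whose product cuts pectin, was higher by 6.48 ± 0.12, and xyloglucan endotransglucosylase/hydrolase 23 (LOC100261550) was lower at -8.99 ± 0.31. The storage list had 48 genes lower and 19 higher of 78 (the same adjusted over the list alone, camera adjusted p = 1.46e-12, 0.249 with an estimated correlation).

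For the monolignol steps at day 45, CAD (2.01 ± 0.13, adjusted p = 8.9e-09), C3H (1.97 ± 0.22, adjusted p = 1.75e-06) and HCT (1.81 ± 0.30, adjusted p = 0.000102) were higher in ZP. F5H (-2.15 ± 0.22, adjusted p = 7.28e-07) and 4CL (-0.78 ± 0.18, adjusted p = 0.00148) were lower. Median-ratio scaling gave 1.07 for CAD, 1.04 for C3H, 0.90 for HCT and -1.70 for 4CL. CCR was higher by 0.44 ± 0.12 (adjusted p = 0.0049) but turned to a called -0.50 after that scaling. Its call was lost after quantile normalization (0.00) and rescaling without the storage list (0.05). C4H at 0.19 and CCoAOMT at 0.06 were not called as deposited but were at -0.75 and -0.88 after median-ratio scaling, and CCoAOMT at -0.31 after quantile normalization. CSE was higher by 0.94 ± 0.38 (adjusted p = 0.0385), a call lost after quantile normalization (0.35), rescaling (0.56) and median-ratio scaling (0.01), and without MH day 45 replicate 2 (0.57), ZP day 45 replicate 1 (0.97) or ZP day 45 replicate 2 (0.90). PAL, lower at -0.28 ± 0.12 (adjusted p = 0.0474), was at -1.22, -0.83 and -0.66 after median-ratio scaling, quantile normalization and rescaling. At -0.28 its call was lost with the replicate block (adjusted p = 0.0522) and with only the 2 groups compared in the fit (0.121). It was lost too without MH day 45 replicate 2 (-0.18), ZP day 45 replicate 1 (-0.32), ZP day 45 replicate 2 (-0.23), or, at an unchanged -0.28, without either library of MH day 61 or ZP day 35 or without ZP day 55 replicate 1. The list of 69 genes had 37 higher and 24 lower (the same adjusted over the list alone; 30 and 32 after median-ratio scaling; camera adjusted p = 0.267, 0.49 with an estimated correlation); the test pointed down while the median was 0.49, or -0.05 after that scaling.

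In all, 9972 genes were called at day 45, 7556 higher and 2416 lower, with a median of 0.682 over all genes. Quantile normalization gave 5128 and 4844, and median-ratio scaling 5169 and 4770.

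At day 55 defence genes were among the largest rises in ZP. Yet the pathogenesis-related list held 5.99% of FPKM in MH and 1.95% in ZP. PR1 stood at 939 ± 313 FPKM in ZP and 0.528 and 0 in the MH libraries (9.53 ± 0.24), PR10.2 at 2752 ± 398 against 16.4 ± 5.43 (7.33 ± 0.21) and MLP-like protein 28 (LOC100262819) at 175 ± 33.2 against 0.128 ± 0.0882 (7.28 ± 0.17). The other rises of the fixed rule were NRT1/PTR family 3.1 (LOC100250961, 7.80 ± 0.11), of a family of nitrate and peptide transporters, and the pectinesterase inhibitor LOC104877746 (7.64 ± 0.22). Of 79 pathogenesis-related genes 52 were higher and 13 lower (52 and 14 adjusted over the list alone; 43 and 21 after median-ratio scaling), but the list was not called (camera adjusted p = 0.163, 0.488 with an estimated correlation), and its endochitinase LOC100255900 was among the largest falls (-11.46 ± 1.36). The other falls were cruciferin CRU1 (-12.55 ± 1.92), basic 7S globulin (-11.94 ± 1.36), the lipid-transfer protein LOC100266074 (-11.57 ± 1.50) and 2S albumin (-10.23 ± 1.29). CRU1, the 7S globulin, this lipid-transfer protein and the endochitinase stood at 0.118 to 1.37 FPKM in replicate 1 of ZP and at 24.5 to 75 in replicate 2. The 10 genes had adjusted p-values of at most 4.18e-05, and the libraries of the varieties did not overlap.

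Photosynthesis had its largest median difference at day 55, 4.46 over 39 genes (3.68 after median-ratio scaling), with 38 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 3.26e-07, 0.488 with an estimated correlation). Photosystem I subunit N (LOC100232935) stood at 182 ± 28.1 FPKM in ZP and 0.649 ± 0.136 in MH (6.78 ± 0.13), and the chlorophyll a-b binding protein LOC100250504 was higher by 5.97 ± 0.20. Beside it, 96 of 131 pericarp ripening markers were higher and 18 lower (the same adjusted over the list alone; camera adjusted p = 0.0907, 0.488 with an estimated correlation). The storage list had 50 lower and 17 higher of 78 (the same adjusted over the list alone, camera adjusted p = 2.96e-13, 0.415 with an estimated correlation). All 7 stilbene synthases, which make resveratrol, were higher (7 and 0 adjusted over the list alone; 4 and 0 after median-ratio scaling; camera adjusted p = 0.128, 0.532 with an estimated correlation), for example LOC100263437 by 2.57 ± 0.30. TRANSPARENT TESTA 1 (LOC100264302) was listed at 0 in the MH libraries and stood at 16.9 ± 1.46 FPKM in ZP, and TRANSPARENT TESTA 16, a MADS-box gene of the seed coat, was higher by 3.22 ± 0.14. Of the skin markers, an anthocyanin malonyltransferase-like gene (LOC100259716) was higher by 4.17 ± 0.10 (7.11 with a pseudocount of 0.1); 21 of 25 skin markers were higher and 2 lower (21 and 3 adjusted over the list alone; camera adjusted p = 0.0907, 0.488 with an estimated correlation). CESA7 and the laccase-4 gene LOC100267265 were higher by 2.74 ± 0.13 and 2.65 ± 0.17. The 7 genes given with a change here had adjusted p-values of at most 2.89e-06.

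Among the monolignol genes at day 55, CAD (1.94 ± 0.13, adjusted p = 1.04e-08) and HCT (1.38 ± 0.30, adjusted p = 0.000963) were higher. F5H (-2.90 ± 0.22, adjusted p = 3.17e-08), CCoAOMT (-0.76 ± 0.15, adjusted p = 0.000304), 4CL (-0.75 ± 0.18, adjusted p = 0.00196), PAL (-0.53 ± 0.12, adjusted p = 0.00117) and C4H (-0.45 ± 0.12, adjusted p = 0.00409) were lower. Median-ratio scaling gave 1.08 for CAD, -1.62 for CCoAOMT, -1.60 for 4CL, -1.39 for PAL and -1.31 for C4H. The HCT call was lost after that scaling (0.55) and quantile normalization (0.64). The C4H call was lost with only the 2 groups compared (adjusted p = 0.102). C3H was higher by 0.50 ± 0.22 (adjusted p = 0.0476), a call lost after median-ratio scaling (-0.34), quantile normalization (-0.16) and rescaling without the storage list (0.24), and with only the 2 groups compared (adjusted p = 0.122). It was lost too without MH day 55 replicate 2 (0.22) or ZP day 55 replicate 2 (0.32) and, at an unchanged 0.50, without any 1 of the libraries of MH day 45, MH day 61, ZP day 35 or ZP day 61, and it rose to 0.79 without MH day 55 replicate 1. CCR at 0.16 and CSE at -0.03 were not called; CCR was called at -0.70 after median-ratio scaling and -0.32 after quantile normalization. Of the list's 69 genes 34 were higher and 27 lower (the same adjusted over the list alone; 27 and 33 after median-ratio scaling; camera adjusted p = 0.121, 0.488 with an estimated correlation), its test pointing down while the median was 0.32, or -0.29 after that scaling.

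Calls at day 55 came to 9887 genes, 7191 higher and 2696 lower, with a median of 0.642 over all genes. They split into 5133 and 5138 after quantile normalization and 5302 and 4839 after median-ratio scaling.

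At day 61 lipid-transfer proteins moved both ways. LOC100243960 (non-specific lipid-transfer protein 1-like) stood at 3991 ± 1833 FPKM in MH and 1.52 ± 1.69 in ZP (-10.73 ± 0.66), whereas a lipid transfer protein precursor (LOC100232872) stood at 8.58 ± 0.361 against 2503 ± 245 (8.03 ± 0.29). Also higher in ZP were LOC100244704 (7.35 ± 0.29) and a gene model without a RefSeq name (7.33 ± 0.30), described as lipid-transfer proteins, the homeobox-leucine zipper protein ATHB-12 (LOC100252202, 7.37 ± 0.22) and MLP-like protein 28 (7.22 ± 0.17). Lower were basic 7S globulin (-9.29 ± 1.36), cruciferin CRU1 (-9.13 ± 1.92), a glycine-rich cell wall protein-like gene (LOC132254747, -8.68 ± 0.74) and the lipid-transfer protein LOC100266074 (-8.41 ± 1.50). The adjusted p-values of these 10 genes were at most 0.000712. In each, both libraries of 1 variety lay above both of the other.

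Seed storage and desiccation had 53 lower and 17 higher of 78 genes at day 61 (53 and 18 adjusted over the list alone, camera adjusted p = 2.18e-14), with a median of -3.35, or -4.22 after median-ratio scaling. The late embryogenesis abundant protein (LOC100267524), of a family tied to desiccation, differed by -8.02 ± 0.34. Photosynthesis had 36 higher and 1 lower of 39 (37 and 1 adjusted over the list alone, camera adjusted p = 2.32e-05); a Rubisco small chain gene (LOC100267942) stood at 643 ± 36 FPKM in ZP and 15.6 ± 3.98 in MH (5.30 ± 0.23). Pericarp ripening markers had 86 higher and 12 lower of 131 (the same adjusted over the list alone, 69 and 26 after median-ratio scaling, camera adjusted p = 0.169). Organelle-encoded RNA, included as a sign of RNA handling, had 5 of 7 genes lower and 1 higher (the same adjusted over the list alone, 6 and 0 after median-ratio scaling, camera adjusted p = 0.0441, 0.0602 with the block within each variety). The adjusted p with an estimated correlation was 0.341 for the storage list and 0.642 for photosynthesis, pericarp markers and organelle RNA. Wall genes differed by 3.67 ± 0.15 (COBRA-like protein 4, LOC100244586), 3.18 ± 0.13 (CESA7, LOC100248512) and 2.98 ± 0.18 (NAC domain-containing protein 73, LOC100267787). These 3 genes had adjusted p-values of at most 5.17e-09.

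The monolignol genes higher in ZP at day 61 were CAD (2.14 ± 0.13, adjusted p = 4.85e-09), HCT (1.11 ± 0.30, adjusted p = 0.00488) and C3H (0.98 ± 0.22, adjusted p = 0.000985). Those lower were F5H (-2.11 ± 0.22, adjusted p = 9.43e-07), 4CL (-0.68 ± 0.18, adjusted p = 0.00428), C4H (-0.49 ± 0.12, adjusted p = 0.00233) and PAL (-0.39 ± 0.12, adjusted p = 0.00961). Median-ratio scaling gave 1.29 for CAD, -1.53 for 4CL, -1.35 for C4H and -1.25 for PAL. The calls of HCT and C3H were lost after that scaling (0.29 and 0.16) and quantile normalization (0.45 and 0.36). CCR was higher by 0.64 ± 0.12 (adjusted p = 0.000298), a call lost at -0.21 and 0.24 in the same way. CSE at 0.41 and CCoAOMT (LOC100243978, 217 FPKM in MH and 217 in ZP) were not called, though CCoAOMT was after median-ratio scaling (-0.86). The PAL call was lost with only the 2 groups compared (adjusted p = 0.0583) and without MH day 61 replicate 2 (-0.34) or ZP day 61 replicate 2 (-0.29), and the HCT call without ZP day 61 replicate 1 (0.90). Over the list of 69 genes 33 were higher and 23 lower (the same adjusted over the list alone; 24 and 31 after median-ratio scaling; camera adjusted p = 0.251, 0.642 with an estimated correlation), the test pointing down while the median was 0.18, or -0.07 after that scaling.

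The count at day 61 was 9432 genes, 7012 higher and 2420 lower, with a median of 0.555 over all genes. Quantile normalization gave 4888 in either direction, and median-ratio scaling 5066 and 4709.

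**Figure D4:**
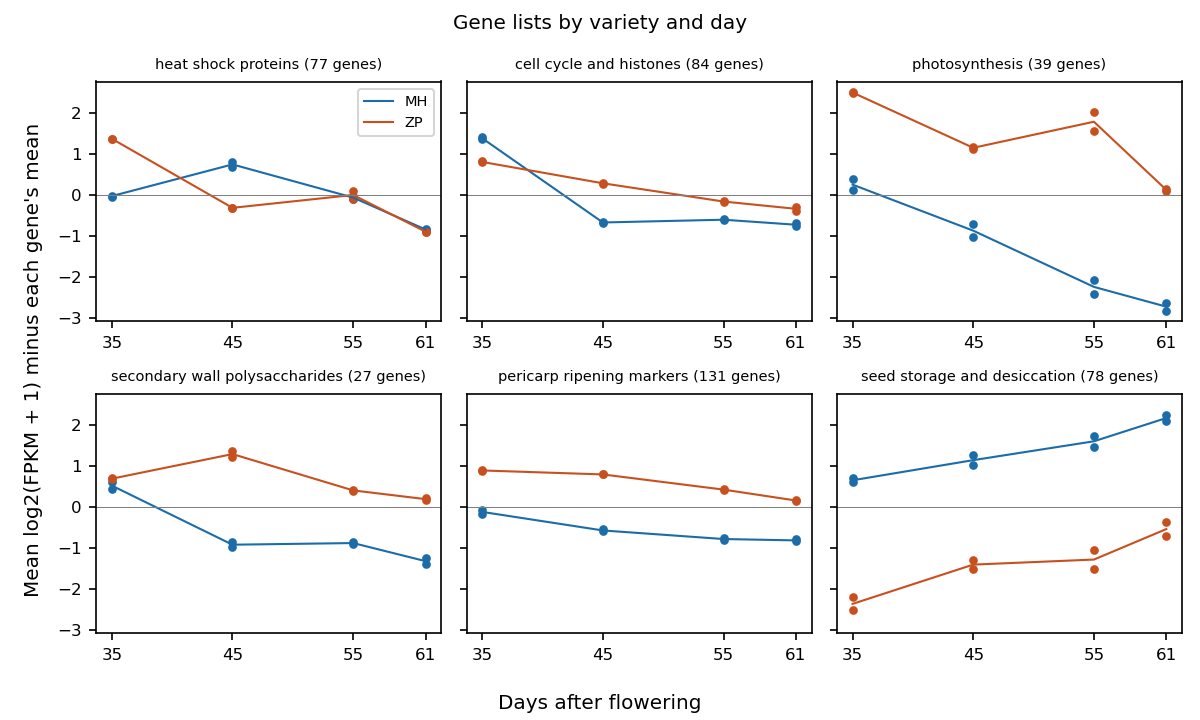
Mean over each of 6 gene lists of log2(FPKM + 1) minus the gene's mean over all libraries (y axis) against days after flowering (x axis), without rescaling; points are libraries, lines join means of 2 libraries, blue for MH and orange for ZP. Photosynthesis lay higher in ZP on each day, also after median-ratio scaling (1.56 and 2.02 against -2.08 and -2.40 at day 55), and heat shock genes were higher in ZP at day 35 (1.38 and 1.37 against -0.01 and -0.04) and lower at day 45 (-0.31 and -0.31 against 0.80 and 0.70), on both days also after that scaling.

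Within MH, genes that rose from day 35 to day 61 included 3 of the storage and desiccation list. The late embryogenesis abundant protein (LOC100267524) went from 0.135 ± 0.109 to 433 ± 83.6 FPKM (8.57 ± 0.34), dehydrin 1a (LOC100232959) changed by 7.71 ± 0.34 and a seed maturation protein (LOC100257252) from 0.248 ± 0.0437 to 153 ± 15.7 (6.95 ± 0.27). The largest rises also held a class II heat shock gene (LOC100262906, 10.20 ± 0.32), MRIP1, a proline-rich extensin-related gene (10.19 ± 0.27), the glycine-rich wall protein gene LOC132254747 (9.85 ± 0.74) and the lipid-transfer protein LOC100243960 (9.23 ± 0.66). Among the largest falls were early nodulin-like protein 1 (LOC100267820, -7.72 ± 0.27), the pectinesterase inhibitor LOC104877746 (-7.62 ± 0.22), and the transcription factor genes TCP8 (LOC104879624, 168 ± 34.8 FPKM at day 35 and listed at 0 at day 61), a myb-related protein (LOC100246422, -7.26 ± 0.17) and zinc-finger homeodomain protein 4-like (LOC100250800, -7.19 ± 0.18). Adjusted p-values of these 12 genes were between 2.82e-12 and 7.34e-08, and the 2 libraries of day 61 did not overlap those of day 35.

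Of 78 storage and desiccation genes 36 rose and 14 fell in MH (the same adjusted over the list alone, 46 and 9 after median-ratio scaling, camera adjusted p = 7.81e-11). Cell cycle and histone genes fell in 75 of 84 cases and rose in 3 (76 and 3 adjusted over the list alone, camera adjusted p = 1.35e-08), with cyclin-D4-2 (LOC100265861) going from 36.8 ± 3.66 to 0.38 ± 0.26 FPKM (-4.78 ± 0.18) and cyclin-dependent kinase B2-1 (LOC100254782) changing by -4.75 ± 0.16. Photosynthesis genes fell in 37 of 39 cases with no rise (37 and 0 adjusted over the list alone, camera adjusted p = 1.74e-08), among them a chlorophyll a-b binding protein (LOC100252004, -5.20 ± 0.32). Secondary wall polysaccharide genes fell in 23 of 27 cases and rose in 2 (24 and 2 adjusted over the list alone, camera adjusted p = 0.000955), with fasciclin-like arabinogalactan protein 11 (LOC100248323) at -4.30 ± 0.18 (-7.17 with a pseudocount of 0.1) and a COBRA-like protein 4 gene (LOC100258803) at -4.03 ± 0.18. The organelle RNA list rose in 6 of 7 genes (6 and 0 adjusted over the list alone, camera adjusted p = 0.00158), at a share that rounded to 0% of FPKM on both days. The ethylene list was called upwards (camera adjusted p = 0.00191) although 23 of 80 genes rose, 22 fell (23 and 21 adjusted over the list alone) and its median was -0.005, or 0.25, with 36 rising and 16 falling, after median-ratio scaling. ERF110 (LOC100262406) rose by 3.81 ± 0.17 (6.12 with a pseudocount of 0.1), and an AP2-like gene described as AIL6 (LOC100854470), of a family known for meristem and embryo growth, not for ethylene, changed by -5.18 ± 0.21. With an estimated correlation the adjusted p was 0.328 for storage and 0.209 for cell cycle. It was 0.48 for photosynthesis and wall polysaccharides and 0.333 for organelle RNA and ethylene.

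In MH, PAL (0.95 ± 0.12, adjusted p = 1.07e-05) and C4H (0.42 ± 0.12, adjusted p = 0.00777) rose from day 35 to day 61. C3H (-2.39 ± 0.22, adjusted p = 4.31e-07), CCR (-1.76 ± 0.12, adjusted p = 3.1e-08), CSE (-1.32 ± 0.38, adjusted p = 0.00803), F5H (-1.12 ± 0.22, adjusted p = 0.000454) and HCT (-1.05 ± 0.30, adjusted p = 0.00769) fell. 4CL at 0.18, CCoAOMT at 0.06 and CAD at -0.26 were not called, though CAD was with a replicate block within MH (adjusted p = 0.0253). After median-ratio scaling they were called at 0.84, 0.74 and 0.42, as was 4CL at 0.50 after quantile normalization. PAL was at 1.62, C4H at 1.09 and CCR at -1.09. Calls were lost after that scaling for HCT (-0.42), CSE (-0.66) and F5H (-0.50), and after quantile normalization for HCT (-0.59) and CSE (-0.90), while F5H was at -0.57. The C4H call was lost with only the 2 groups compared (adjusted p = 0.0602). Calls were also lost for C4H without MH day 35 replicate 2 (0.33), for HCT without MH day 35 replicate 1 (-0.64) or MH day 61 replicate 2 (-0.87), and for CSE without MH day 35 replicate 1 (-0.90) or MH day 61 replicate 2 (-0.98). Of the 69 genes of the list 15 rose and 36 fell (the same adjusted over the list alone; 24 and 27 after median-ratio scaling, with a median of -0.17 against -0.48; camera adjusted p = 0.933, 0.975 with an estimated correlation). Altogether 1999 genes rose and 6588 fell, 8587 in all, with a median of -0.43. The split was 4170 and 3943 after quantile normalization and 3879 and 4428 after median-ratio scaling.

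Within ZP, the same interval brought storage transcripts up from a low level. Legumin A (LOC100241281) rose from 0.0191 and 18.2 FPKM in replicates 1 and 2 of day 35 to 1063 ± 580.1 FPKM (7.79 ± 0.99), an oleosin (LOC100249321) from 0.50 ± 0.19 to 263 ± 142 (7.35 ± 0.50), 2S albumin (LOC100252101) from a listed 0 and 19 in those libraries to 671 ± 493 (7.01 ± 1.29) and a further oleosin (LOC100255962) by 5.91 ± 0.46. The class IV chitinase CHI4D (7.56 ± 0.16), endochitinase A (LOC132253710, annotated as a long non-coding RNA, 7.09 ± 0.17) and ATHB-12 (7.06 ± 0.22) completed the largest rises. The largest falls were the thaumatin-like protein LOC100261232 (-8.15 ± 0.35), a GDSL esterase/lipase (LOC100243401, -7.95 ± 0.15), a polygalacturonase gene (LOC100241353, -7.71 ± 0.13), a gene described as a ribonuclease H protein and annotated as a long non-coding RNA (LOC109122422, -7.44 ± 0.11) and a putative lipid-transfer protein DIR1 (LOC100256803, -7.42 ± 0.27). The 12 genes had adjusted p-values between 2.64e-13 and 0.000319, and the 2 libraries of day 61 did not overlap those of day 35.

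Storage and desiccation genes rose in 53 of 78 cases and fell in 8 in ZP (56 and 8 adjusted over the list alone, camera adjusted p = 8.11e-08). Heat shock genes fell in 60 of 77 cases and rose in 10 (60 and 11 adjusted over the list alone, camera adjusted p = 1.39e-09, and 0.0343 with an estimated correlation). Heat shock protein 83 (LOC100265661) went from 853 ± 3.0 to 6.31 ± 0.645 FPKM (-6.87 ± 0.19). Cell cycle and histone genes fell in 65 of 84 cases and rose in 7 (67 and 8 adjusted over the list alone, camera adjusted p = 3.78e-08), with the replication factor MCM4 (LOC100262415) at -3.48 ± 0.13. Photosynthesis genes fell in 36 of 39 cases and rose in 1 (the same adjusted over the list alone, camera adjusted p = 1.02e-09). Ethylene genes rose in 59 of 80 cases and fell in 7 (the same adjusted over the list alone, camera adjusted p = 1.47e-07), among them ERF011-like (LOC100245542, 4.24 ± 0.22) and the oil regulator WRI1 (3.38 ± 0.20). Skin markers rose in 16 of 25 cases and fell in 3 (the same adjusted over the list alone, camera adjusted p = 0.00254). All 7 stilbene synthases rose (7 and 0 adjusted over the list alone, 4 and 0 after median-ratio scaling, camera adjusted p = 0.00905). Pericarp ripening markers fell in 69 of 131 cases and rose in 39 (70 and 39 adjusted over the list alone, camera adjusted p = 0.0317), and wall polysaccharide genes fell in 17 of 27 cases and rose in 3 (the same adjusted over the list alone, camera adjusted p = 0.0448). The adjusted p with an estimated correlation was 0.284 for storage and pericarp markers, 0.0851 for cell cycle and ethylene, and 0.249 for skin markers. It was 0.45 for photosynthesis, 0.453 for stilbene synthases and 0.648 for wall polysaccharides.

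Of the monolignol genes in ZP, CAD (LOC100257308, 1.46 ± 0.13, adjusted p = 3.65e-07), CCoAOMT (1.07 ± 0.15, adjusted p = 2.23e-05) and PAL (0.37 ± 0.12, adjusted p = 0.0139) rose. CSE (-1.11 ± 0.38, adjusted p = 0.0214), F5H (-0.77 ± 0.22, adjusted p = 0.00628) and C4H (-0.41 ± 0.12, adjusted p = 0.00854) fell. CAD went from 194 ± 0.513 to 534 ± 22.5 FPKM. 4CL (-0.31), HCT (-0.47), C3H (0.24) and CCR (-0.16) were not called; 4CL, HCT and C3H were with only the 2 groups compared (adjusted p = 0.0209, 0.0406 and 0.0176), where the F5H call was lost (0.0641). Calls were lost after median-ratio scaling for CSE (-0.99) and C4H (-0.30) and after rescaling without the storage list for PAL (0.39, adjusted p = 0.0507). They were lost too for PAL without ZP day 35 replicate 2 (0.34) or ZP day 61 replicate 1 (0.27) and for C4H without ZP day 35 replicate 1 (-0.37) or ZP day 61 replicate 2 (-0.34). They were also lost for CSE without any 1 of the 4 libraries compared (-1.16 to -1.06) and for F5H without ZP day 61 replicate 1 (-0.38); without ZP day 61 replicate 2 F5H was at -1.17, and with a pseudocount of 0.1 at -1.26. Of the list's 69 genes 25 rose and 21 fell (the same adjusted over the list alone; camera adjusted p = 0.642, 0.772 with an estimated correlation, the test pointing up while the median was -0.03, or 0.04 after median-ratio scaling). Altogether 4027 genes rose and 4425 fell in ZP, 8452 in all, with a median of -0.01; after median-ratio scaling 4321 rose and 3986 fell.

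For the interaction (3 terms together), the value given is the difference ZP minus MH at day 61 less that at day 35. Zinc-finger homeodomain protein 4-like (LOC100250800) stood at 619 ± 3.36 FPKM in MH and 0 and 0.074 in the ZP libraries at day 35, and at 3.26 and 16.4 at day 61, a value of 11.22 ± 0.25. Zinc-finger homeodomain protein 2-like (LOC100245660, 10.06 ± 0.32), a DC2.15 gene that overlaps another gene (LOC100253899, 9.94 ± 0.22), sucrose synthase 2 (LOC100243135, 8.39 ± 0.37) and ATHB-12 (7.68 ± 0.31) also had large positive values. Negative values were found for the thaumatin-like protein LOC100261232 (-9.71 ± 0.50), the GDSL esterase/lipase genes LOC100259984 (-8.53 ± 0.20) and LOC132254247 (-8.28 ± 0.20), the lipid-transfer protein LOC100243960 (-8.14 ± 0.93) and a probable aspartyl protease (LOC104880161, -8.03 ± 0.25). The adjusted p-values of these 10 genes were at most 2.21e-05.

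Heat shock genes had the smallest interaction p of the lists. 74 of 77 were called for interaction (74 adjusted over the list alone), and the variety difference moved down from day 35 to day 45 (camera adjusted p = 2.32e-27, and 0.000847 with an estimated correlation) and from day 35 to day 61 (camera adjusted p = 2.1e-10, and 0.024 with an estimated correlation). A class I gene (LOC100263791) had a value of -4.95 ± 0.21 and the class II gene LOC100262906 one of -7.64 ± 0.45. From day 35 to day 45 the variety difference moved up for cell cycle and histone genes (camera adjusted p = 5.29e-05), wall polysaccharides (0.000556), ethylene (0.0169) and skin markers (0.0399), and down for photosynthesis (0.00115) and gibberellin (0.028). From day 35 to day 61 it moved up for cell cycle (0.0335) and wall polysaccharides (0.039), and down for organelle RNA (0.0266), pericarp markers (0.0266), cell death (0.028) and gibberellin (0.028). With an estimated correlation the adjusted p of these 12 calls lay between 0.218 and 0.708. Called for interaction, over all genes and adjusted over the list alone, were 75 and 75 of 84 cell cycle genes, 26 and 26 of 27 wall polysaccharide genes, 73 and 74 of 80 ethylene genes, and 21 and 21 of 25 skin markers. The same held for 37 and 38 of 39 photosynthesis genes, 25 and 25 of 29 gibberellin genes, 5 and 5 of 7 organelle genes, 122 and 122 of 131 pericarp markers, and 20 and 20 of 29 cell death genes.

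The wall genes fasciclin-like arabinogalactan protein 11 (LOC100250171) and CESA7 had interaction values of 3.80 ± 0.28 and 2.94 ± 0.18, and the laccase-4 genes LOC100267265 and LOC100240808 values of 3.80 ± 0.23 and 3.28 ± 0.27. Other members named by the rule were an oleosin (LOC100249321, 7.41 ± 0.71), the Rubisco small chain gene LOC100256536 (7.16 ± 0.33), WRI1 (6.13 ± 0.28) and WUSCHEL-related homeobox 2 (6.14 ± 0.27). Stilbene synthase 1 (LOC100263437) was at 3.45 ± 0.42, or 7.06 with a pseudocount of 0.1. The adjusted p-values were at most 2.2e-05. Among the monolignol genes, C3H (2.63 ± 0.30, adjusted p = 1.61e-06), CAD (1.71 ± 0.18, adjusted p = 5.38e-06) and CCR (1.61 ± 0.17, adjusted p = 8.82e-06) were called. So were CCoAOMT (1.00 ± 0.21, adjusted p = 0.000593), C4H (-0.83 ± 0.17, adjusted p = 0.000841) and PAL (-0.58 ± 0.17, adjusted p = 0.00886). 4CL (-0.49), HCT (0.58), F5H (0.34) and CSE (0.21) were not (adjusted p = 0.143, 0.0777, 0.0912 and 0.386).

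Median-ratio scaling gave interaction values of -1.13 for PAL, -1.39 for C4H, 0.45 for CCoAOMT and 1.06 for CCR. 4CL was called after it (-1.04), after quantile normalization (-0.74) and after rescaling without the storage list (-0.55). HCT was called with the replicate block (0.58, adjusted p = 0.0371). The PAL call was lost without ZP day 35 replicate 1 (-0.54). Calls were gained for 4CL without MH day 55 replicate 2 (-0.49), for HCT without MH day 35 replicate 2 (0.99), MH day 45 replicate 1 or either MH day 55 library (0.58 each), and for F5H without ZP day 61 replicate 1 (0.74) or replicate 2 (-0.05). Of the 69 monolignol genes 60 were called for interaction (61 adjusted over the list alone), with no call of the list as a whole (camera adjusted p = 0.349 from day 35 to day 45 and 0.716 from day 35 to day 61; 0.643 and 0.835 with an estimated correlation). Altogether 9969 genes were called for interaction, 6827 with a positive and 3142 with a negative value; after median-ratio scaling the split was 5409 and 4443.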

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

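The tests of explanations for 3 patterns (low storage transcripts, the general shift and photosynthesis) and the splits that keep groups whole were chosen only after the results were seen; the other splits of the libraries were planned. The time course differed between the varieties for 9969 genes by the interaction test. Of 100 splits of the libraries 2 gave as many genes, the real one included; the other, with 11927, exchanges the varieties at days 55 and 61. This cannot decide on chance, since exchanging whole days turns a difference between the varieties into an interaction, and mixing the varieties in a group raises the spread within it. All 8 splits that keep groups whole gave as many, with up to 12026. For the average difference 1 of 100 splits, the real one, gave as many as 11204 genes, against 8887 in the highest other. This cannot decide on chance either, as mixing raises the spread. With groups kept whole 1 of 8 gave as many, the real one, against 10395 in the highest other. Still, 8 splits are too few for a share under 0.05.

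The heat shock list differed between the varieties in its change from day 35 to day 45 (camera adjusted p = 2.32e-27). Conditions at each group's harvest were not given and cannot be told apart from variety here. The variety difference had opposite signs on different days, at 1 or more on the log2 scale and under both scalings, in 22 named genes. Their interaction adjusted p-values were 7.26e-09 and 1.01e-08 for the laccase-4 genes LOC100240808 and LOC100267265, 8.01e-09 for LOC100250171, 2.4e-07 and 8.61e-08 for the NAC genes LOC100250388 and LOC100267787, and 1.61e-06 for C3H (LOC100263633). For heat shock genes they were 2.19e-10 (LOC100263791), 2.16e-07 (LOC100265661), 6.39e-07 (LOC100268056) and 1.32e-08 (LOC104881029). Cell cycle genes had 4.46e-08 (LOC100254782) and 6.02e-07 (LOC100257988). Transcription factor genes had 8.25e-10 (LOC100246422), 2.31e-11 (LOC100250800) and 5.31e-10 (LOC104879624). The rest were 1.08e-10 (CHI4D), 2.28e-11 (LOC100253899), 4.87e-08 (LOC100256803), 1.11e-08 (LOC100261232), 1.37e-08 (LOC100267820), 2.78e-11 (LOC132254247) and 6.34e-09 (MRIP1). A further 7 named genes changed in opposite directions over time in MH and ZP. They were LOC100232872 (-3.54 and 1.26), LOC100232922 (4.09 and -3.04), LOC100243135 (-2.87 and 5.52), LOC100245660 (-6.77 and 3.30), WRI1 (LOC100250488, -2.74 and 3.38), LOC100256536 (-3.67 and 3.49) and LOC100267696 (-1.85 and 3.07). Groups held 2 libraries, too few to test for a library far from the others.

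Storage transcripts were low in ZP, and before day 61 those of cruciferin CRU1 (LOC100246409) and basic 7S globulin (LOC100240860) lay almost wholly in replicate 2; the oleosin LOC100249321 stood at 24.5 and 21.7 FPKM in the 2 libraries of day 45. Reads carried over from MH would give all 8 storage genes of at least 1000 FPKM in MH the same ratio in a library, and on days 45, 55 and 61 the smallest SD of the log2 ratio to the mean of all MH groups was 1.73 (lower 95% bound 1.14), which argues against carry-over as the whole signal but leaves it open for genes seen in replicate 2 alone. On the 4 days the smallest SD against MH of the same day was 1.99 (lower bound 1.32), which argues against a small share of ZP ovules with the profile of MH ovules as the whole signal. At day 35 replicate 2 had an SD of 2.55 (95% interval 1.69 to 5.19; ratios of 0.0233% to 4.35%) against MH of that day, which argues against carry-over from it alone, but of 0.56 (0.37 to 1.14; 0.0275% to 0.0818%) against the mean of all MH groups, so carry-over from MH libraries of all days and real low expression cannot be told apart there. The variety itself remains open as an untested biological explanation.

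Most genes had higher FPKM in ZP, by a median of 0.682 at day 45. Deeper ZP libraries are argued against by day 61, where the log2 ratio of depth was -0.286 and the shift 0.555. Rescaled to the table total, the shift at days 45, 55 and 61 was 0.974, 0.96 and 0.852; without the 10 most abundant genes of each library in that total it was 0.339, 0.309 and 0.312, and without 100 of each 0.224, 0.161 and 0.174. Abundant genes may thus account for most of it, but the 10 alone not for all. Selection of genes by the authors stays open, as 47.7% of protein-coding genes were in the deposited file, and so does a difference between the varieties in total RNA.

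Photosynthesis transcripts were higher in ZP by a median of 4.46 at day 55. A lower share of embryo and endosperm would raise all other tissues alike, but the photosynthesis median lay above those of 4 other tissue lists by at least 2.5 (95% interval 0.77 to 4.21), which argues against it as the whole cause. Pericarp or skin carried along with the ovules could add such transcripts: 8 of 131 pericarp ripening markers were raised by at least the photosynthesis median, which does not decide it. A difference in ovule greening between the varieties is open and was not tested.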

How the results depend on the processing

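Median-ratio scaling, rescaling without the storage list, the exchanged block, the block within each variety and camera after quantile normalization are the tests chosen only after the result was seen; the others were planned. The alternatives built on count-based tools were not run, since the values are FPKM. Of 272 named gene results, all 272 kept their direction and side of the threshold with a pseudocount of 0.1 and with no filter, 255 after quantile normalization, 247 after median-ratio scaling and 262 after rescaling without the storage list. With only the 2 groups compared 192 of 201 did, with the added fold limit 211 of 237 and, for the interaction at an adjusted p under 0.01, 35 of 35. Over 4352 values with 1 library left out, 4296 did, 43 lost and 12 gained a call and 1 changed sign. A left-out library leaves its group with 1 library, assumed to vary like the other groups.

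Among named genes signs changed in monolignol genes only. The others were picked for large changes, which favours kept calls. Median-ratio scaling put C4H at -0.75 and CCoAOMT at -0.88 at day 45. It put CCR at -0.50, -0.70 and -0.21 at days 45, 55 and 61 and -0.67 on average. It put C3H at -0.34 at day 55 and -0.27 on average, and CAD at 0.42 over time in MH. After quantile normalization CCoAOMT was at -0.31 at day 45, CCR at -0.32 at day 55 and -0.30 on average, and C3H at -0.16 at day 55 and -0.07 on average. CCR was at -0.20 on average after rescaling without the storage list. The F5H (LOC100250277) interaction value was -0.05 without ZP day 61 replicate 2 and 0.74 without ZP day 61 replicate 1. For all of these the cause was not tested.

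With the added fold limit, which can only remove calls, 5595, 6272, 6477 and 5824 genes were called at days 35, 45, 55 and 61, 5713 on average, 4441 in MH and 4232 in ZP. The interaction gave 8552 at an adjusted p under 0.01. With 1 library left out the counts lay between 8699 and 9866 at day 35, 9245 and 10101 at day 45, 9186 and 9949 at day 55, 8725 and 9583 at day 61, 10815 and 11256 on average, 7272 and 8755 in MH, 7168 and 8637 in ZP and 9022 and 10203 for the interaction. Over the 7 comparisons other than the interaction, the gene list tests made 36 calls with camera, 36 with the replicate block, 35 with the block within each variety, 41 after quantile normalization, 2 with an estimated correlation and 181 with fry, which does not compare a list with other genes. For the interaction camera made 14 calls, 2 of them with an estimated correlation as well.

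Correlations of same-numbered deviations ranged from 0.076 to 0.27 between ZP groups and from -0.597 to 0.083 between the varieties, so the numbers were not shown to pair libraries there, unlike within MH. With the replicate block 9848, 10084, 9992 and 9570 genes were called at days 35, 45, 55 and 61, 11268 on average, 8721 in MH, 8631 in ZP and 10170 for the interaction, and 270 of 272 named gene results stayed on their side of the threshold; PAL at day 45 lost its call (adjusted p = 0.0522) and the HCT interaction gained one (0.0371). With the replicate block within each variety 10341, 10558, 10547 and 10093 genes were called on these days, 11566 on average, 9365 in MH, 9245 in ZP and 11081 for the interaction. No named gene lost its call, and 10 results of monolignol genes gained one: HCT at day 35 (adjusted p = 0.0107), CSE at day 61 (0.0412) and on average (0.000958), CAD in MH (0.0253), 4CL and HCT in ZP (0.0491 and 0.0216), and 4CL, HCT, CSE and F5H for the interaction (0.0311, 0.00168, 0.0127 and 0.0369). Of the lists, cell death gained a call at day 45 (0.049), and calls were lost for organelle RNA at day 61 (0.0602) and pericarp markers in ZP (0.0522). With the ZP numbers of days 55 and 61 exchanged, the replicate block gave 10296 and 9847 genes on those days. At 0.033 to 0.05 FPKM per fragment and kilobase, differences between values near that level were not detectable.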

Other observations

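Median-ratio values here come from tests chosen only after the result was seen; the list tests were planned. The remaining lists were not called by camera for the average difference between the varieties, and their counts were the same adjusted over the list alone. In 12 of them more members were higher than lower in ZP, before and after median-ratio scaling. Of 79 pathogenesis-related genes 60 were higher and 12 lower (44 and 21 after scaling; camera adjusted p = 0.157), of 29 cell death genes 25 and 4 (18 and 7; 0.0932), of 80 ethylene genes 61 and 17 (46 and 20; 0.197), and of 25 skin markers 20 and 3 (18 and 5; 0.139). Class III peroxidases, which like laccases can join monolignols, had 20 higher and 6 lower of 28 (16 and 7; 0.455). Dirigent proteins had 13 and 2 of 17 (13 and 4; 0.192), vascular markers 11 and 0 of 14 (10 and 3; 0.207) and secondary wall regulators 14 and 1 of 15 (10 and 1; 0.0932). Stilbene synthases had 7 and 0 of 7 (4 and 0; 0.3) and laccases 17 and 5 of 24 (11 and 8; 0.52). Auxin genes had 51 and 23 of 80 (40 and 30; 0.724) and gibberellin genes 16 and 10 of 29 (14 and 13; 0.775).

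In other lists the balance turned or was lost with the scaling. Heat shock genes had 40 higher and 27 lower of 77 but 23 and 45 after median-ratio scaling (camera adjusted p = 0.189) and cell cycle genes 48 and 17 of 84 but 19 and 36 (0.52). Ribosomal proteins had 33 and 16 of 57 but 13 and 25 (0.52), cytokinin 24 and 18 of 46 but 16 and 23 (0.289) and sugar genes 21 and 10 of 40 but 14 and 21 (0.586). Flavonoid genes had 11 and 10 of 24 (8 and 13; 0.249) and endosperm and embryo markers 10 and 5 of 16 (7 and 8; 0.675). Lipid and wax genes had 61 and 39 of 108 (48 and 48; 0.3) and abscisic acid genes 12 and 9 of 22 (10 and 10; 0.369). Organelle RNA had 2 higher and 5 lower of 7 under both scalings (0.157). The camera test pointed down while the median and mean as deposited were above 0 for heat shock, cell cycle, ribosomal, cytokinin, sugar, endosperm and embryo, lipid and wax, gibberellin and abscisic acid genes. For flavonoid genes the test and the median (-0.083) pointed down while the mean was 0.279. With an estimated correlation the adjusted p of the lists in these paragraphs lay between 0.474 and 0.812.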
